A study of Homo sapiens with 8 samples.

How the data were processed

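The series holds MYC chromatin immunoprecipitates and inputs of MCF-7 cells treated for 2 h with AM (actinomycin D at 1 µM and MG132 at 10 µM) or DMSO, with 2 samples in each of 4 groups. Samples were grouped by their titles. The single deposited table used here is a peak list for the DMSO immunoprecipitates, with 1 set of values for both samples together. Reads were aligned with Bowtie2 to hg38, and MACS2 and bedtools were used, per the submitters' processing notes. Versions, peak settings and the way replicates were combined are not given in the sources used here. How reads that match several places were treated is not given there either, and this decides whether repeated regions can hold peaks.

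Each peak in the deposited list has a chromosome, start, end, name, score, strand sign and annotation class. The authors' score is a whole number from 113 to 1000, with 30.3% of peaks at the lowest and 39.8% at the highest value, and its unit is not given in the sources used here. The deposited peak names hold another number, called the caller value, whose lowest value is 1.31, just above the −log10 of 0.05, which is 1.30. It has the range of a −log10 p or q value and was used to rank, compare and filter peaks within the list only. Such a value rises with read depth, peak width and DNA copy number as well as with enrichment. The authors' classes are promoter, exon, intron (each for protein-coding transcripts) and intergenic. The strand sign was the same for all peaks and was not used. Starts were taken to count from 0, as in BED files, and were converted to 1-based positions.

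Genes came from a RefSeq gene table of assembly GRCh38, the assembly that hg38 names. It gives the start and end of each gene but neither strand nor transcription start sites. Positions were checked by the share of peaks over a protein-coding gene end, which was 82.4% for promoter-class peaks and 1.99% for the others. The background was 19974 protein-coding genes on the 23 chromosomes that hold peaks. A gene counted as occupied when a promoter-class peak lay within 1 kb of either end, and its strength was the highest caller value among those peaks. Some genes with only a LOC symbol lie on alternate sequences whose positions are not those of the chromosome, and the lists were also tested without them. Gene counts and tests of peak-free regions leave out all genes with only a LOC symbol. Some tRNA genes without a numbered family name appear to lie on such sequences too and were kept among the 443 tRNA genes.

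The 26 gene lists, the rule for named genes, the tests and a part of the other settings tried were fixed before the data were examined. Of 752 list entries, 750 matched by symbol, 1 by synonym (NDUFA4) and 1 had no match (EIF1A). Named genes were those nearest the 10 strongest peaks, the 2 members with the strongest promoter peak of each list past the threshold, all members of the MYC-MAX-MLX network, up to 2 members without a peak per list in alphabetical order, and the textbook targets CAD, NCL, NPM1, ODC1, LDHA, CDK4, TERT and CDKN1A. The text names a part of them, and neighbours that share a peak are named where needed.

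Shares have 95% Wilson intervals, which cover counting error only. Promoter peaks were compared with other peaks by a two-sided permutation test of the difference in median caller value. List occupancy was tested with two-sided Fisher exact tests of members against all other background genes. List strength was tested, for lists with enough occupied members, by a two-sided permutation test of the median against random sets of as many occupied genes. Permutation tests used 100000 resamples, and p-values were adjusted by Benjamini-Hochberg at a threshold of 0.05 over the lists of each test. Genes that share a peak are not independent, and neither test matches genes on expression or promoter sequence.

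On simulated data for the same 19974 genes, the occupancy test called 123 of 260 lists made with an odds ratio of 3 (47.3%) and 0 of 240 unchanged lists. The strength test called 23 of 52 lists made 2-fold stronger (44.2%) and 1 of 48 unchanged lists. The simulation drew each gene separately and so left out peaks shared between neighbours. Its rates of false calls need not hold for the real list. The assignment of peaks to genes was checked by direct search for 300 genes, with 0 disagreements.

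The plan differed from the analysis in these points. Fold enrichment had been planned as the measure of strength, and the caller value replaced it. Genes were to be taken from the list's own assignment to transcription start sites, and gene ends of the reference table replaced it. E-box content, a background matched on CpG density and overlap with reference start sites were not analysed here, since they need a genome or strands. AM against DMSO was not analysed here, since the values used cover DMSO alone. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.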

Results

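The series profiled chromatin binding of MYC, a transcription factor of the basic helix-loop-helix leucine zipper family, in MCF-7 cells, an estrogen receptor-positive human breast cancer line. Cells had received AM, a combination of actinomycin D (1 µM), which blocks transcription, and MG132 (10 µM), which blocks the proteasome, or the solvent DMSO, for 2 h. The 8 samples formed 4 groups of 2, MYC immunoprecipitate and input for each treatment. The design sets MYC binding after AM against binding after DMSO. The values used here came from 1 list of MYC peaks for the DMSO immunoprecipitates, so binding in DMSO-treated cells is described and the AM samples were not analysed here. The list holds no value per sample and no read counts, so replicate spread and sequencing depth are unknown, and intervals and tests describe this peak list rather than separate cultures.

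MYC bound chiefly at promoters of protein-coding transcripts where its peaks were strong, and mostly outside such promoters where they were weak. The list held 47582 peaks on 23 chromosomes, of which 11502 were placed by the authors at promoters of protein-coding transcripts (24.2%, 95% Wilson interval 23.8 to 24.6%). A further 3595 lay in exons (7.56%) and 13956 in introns (29.3%) of such transcripts, and 18529 were classed as intergenic (38.9%). The intergenic class includes peaks over non-coding genes, such as MIR17HG and PVT1. Each peak carries a number given by the authors' peak caller, here called the caller value, whose unit is not given in the sources used here and which was used to rank, compare and filter peaks within the list only. Promoter peaks had a median caller value of 124 (interquartile range 44.4 to 285) and a median width of 1817 bp. Exon, intron and intergenic peaks had medians of 18.2, 14.8 and 16.6 and median widths of 765, 600 and 638 bp.

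When the peaks were ordered by caller value and divided into deciles, promoter peaks made up 7.80% of the weakest decile (values 1.31 to 4.90) and 74.3% of the strongest (231 to 11065). Intergenic peaks made up 44.7% and 14.6% of the same deciles, and intron peaks 37.7% and 7.04%. Among the strongest 476 peaks, 409 were promoter peaks (85.9%), 40 intergenic, 15 intronic and 12 exonic. The median of promoter peaks was 7.72 times that of the other 36080 peaks, which was 15.998 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). With the deposited score, which stops at 1000, the medians were 1000 and 284. Among peaks with the score above its lowest value, the ratio of median caller values was 4.87.

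**Figure D1:**
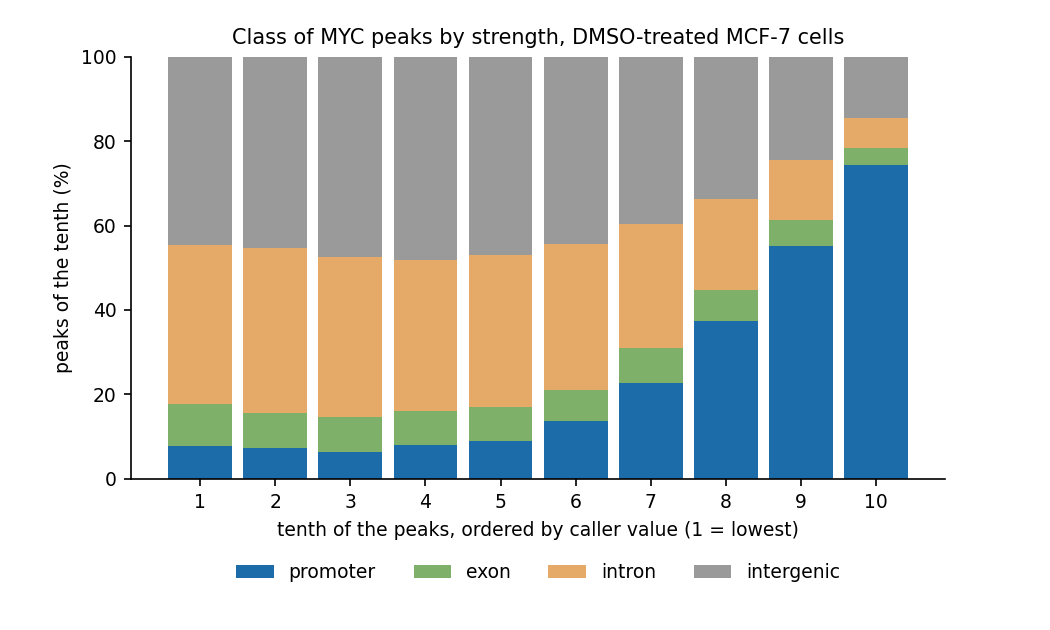
Share of MYC peaks in each of the authors' annotation classes (y axis, percent) by decile of the caller value (x axis, weakest at the left), DMSO-treated MCF-7 cells. Promoter peaks take 7.80% of the weakest decile and 74.3% of the strongest.

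The strongest peak of the list lay at the promoter of GABPB1, which encodes a subunit of the transcription factor GABP (chromosome 15, 50353498 to 50356652, hg38, caller value 11065). The promoter shared by NRAS, a RAS family GTPase, and CSDE1 held the third strongest (chromosome 1, 114716070 to 114717391, 6946). Promoter peaks at GDI2 (5813), at the shared promoter of CCDC47 and DDX42 (5809), at TOP1, which encodes DNA topoisomerase I (5492), at NME1, a nucleoside diphosphate kinase (5084), at the shared promoter of SNX5 and MGME1 (4520) and at G6PC3, a glucose-6-phosphatase (4409), were also among the top 10. The remaining peaks of the top 10 were not at the end of an annotated protein-coding gene. The second strongest, of the promoter class (chromosome 17, 60390789 to 60393677, 7668), lay inside USP32 and 27537 bp from the nearest gene end, that of CHCT1. The fourth (chromosome 7, 4641263 to 4643071, 5931) was intergenic, overlapped no annotated gene and lay 39224 bp from the nearest end of FOXK1, whose own promoter peak had a caller value of 496. This ranking can also reflect DNA copy number, with which the caller value rises. The NRAS, USP32, CCDC47, TOP1, NME1, SNX5 and G6PC3 peaks lay on chromosomes 1, 17 and 20, which carry amplified regions in this line.

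Of 19974 protein-coding genes, 11580 had a promoter-class peak within 1 kb of a gene end (58.0%, 95% Wilson interval 57.3 to 58.7%), and the strongest such peak per gene had a median caller value of 148. Genes with such a peak are called occupied here. Either end of a gene was allowed, and 3523 occupied genes (30.4%) shared their strongest peak with another gene. Among 8948 genes with no other protein-coding gene within 5 kb, 4322 were occupied (48.3%).

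Genes of ribosomes, mitochondria, DNA replication and nucleotide synthesis were occupied almost without exception, whereas genes restricted to liver, muscle, immune cells and neurons were mostly unoccupied. Of 26 gene lists, 20 were occupied more often than the remaining genes, 3 less often, and 3 did not pass the test (two-sided Fisher exact tests, Benjamini-Hochberg adjusted over the 26 lists). All 33 oxidative phosphorylation genes were occupied (Fisher exact test, adjusted p = 2.69e-07), as were 44 of 45 cytosolic ribosomal protein genes (odds ratio 32.0, adjusted p = 3.67e-08), 32 of 33 genes of DNA replication (23.3, 2.27e-06) and 28 of 29 genes of nucleotide synthesis (20.3, 1.33e-05). Liver and muscle genes had 2 of 27 members occupied (odds ratio 0.0578, Fisher exact test, adjusted p = 4.11e-07), immune cell genes 3 of 26 (0.0943, 7.02e-06) and neuronal genes 7 of 25 (0.281, 0.00447). ALB, which encodes serum albumin, and ACTA1, skeletal muscle actin, had no peak, and neither had the monocyte marker CD14 nor the B cell marker CD19. Several occupied members of these lists shared the peak with a neighbour. The peak counted for the macrophage marker CD68 (313) reached MPDU1, that counted for the synaptic vesicle gene SYP (403) reached PRICKLE3, and that for the glutamate receptor gene GRIN1 (514) reached LRRC26 and TMEM210. The CD68 and SYP peaks lay outside these genes themselves.

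The protein synthesis lists were all past the threshold. Nucleolar ribosome biogenesis factors had 38 of 40 members occupied, mitochondrial ribosomal proteins 34 of 36, translation factors 31 of 33, RNA polymerase I and III genes 30 of 33 and aminoacyl-tRNA synthetases 18 of 20, with odds ratios from 6.53 to 13.8 and adjusted p from 1.11e-06 to 0.00355. Lists of general cell upkeep also passed. Lysosome and autophagy genes had 30 of 32 members occupied, proteasome genes 29 of 31, histone genes 29 of 31, RNA polymerase II and elongation genes 27 of 30, chaperones 25 of 28, and spliceosome and mRNA binding genes 32 of 36 (odds ratios 5.81 to 10.9, adjusted p 3.64e-05 to 0.000661). Polyamine and amino acid metabolism (21 of 23, Fisher exact test, adjusted p = 0.00142), luminal and estrogen receptor genes (27 of 30, 0.000426), p53 targets (22 of 25, 0.00254), circadian clock genes (18 of 21, 0.0146) and G1/S and E2F genes (22 of 26, 0.00593) also passed. Glycolysis genes had 15 of 20 members occupied (odds ratio 2.18, Fisher exact test, adjusted p = 0.180) and basal and mesenchymal genes 12 of 25 (0.669, 0.319). The clock call was lost with caller values of at least 10 (odds ratio 2.71, Fisher exact test, adjusted p = 0.0553) or at or above the median (1.59, 0.384), with the score above its lowest value (2.22, 0.135) or at its highest (1.47, 0.392) and without chromosomes 1, 17 and 20 (4.37, 0.0611). Without these chromosomes the clock list held 14 members in place of 21, and its odds ratio stayed near that with all chromosomes (4.35). The G1/S call was lost without these chromosomes (3.10, Fisher exact test, adjusted p = 0.0522), and the luminal call with caller values at or above the median (2.28, 0.0509) or the score at its highest (1.66, 0.209). When any peak over the gene counted, the calls of aminoacyl-tRNA synthetases (odds ratio 3.54), G1/S genes (3.02) and neuronal genes (14 of 25, 0.4998) were lost (Fisher exact test, adjusted p = 0.0892, 0.0892 and 0.121), and among genes with no other gene within 5 kb those of G1/S (5 of 9), clock (4 of 6) and histone genes (3 of 3) were lost (0.747, 0.496 and 0.134). Glycolysis passed with peaks within 3 kb (17 of 20, odds ratio 3.79, Fisher exact test, adjusted p = 0.0242), with peaks of any class at a gene end (0.0417) and with promoter-class peaks inside the gene (0.0391).

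**Figure D2:**
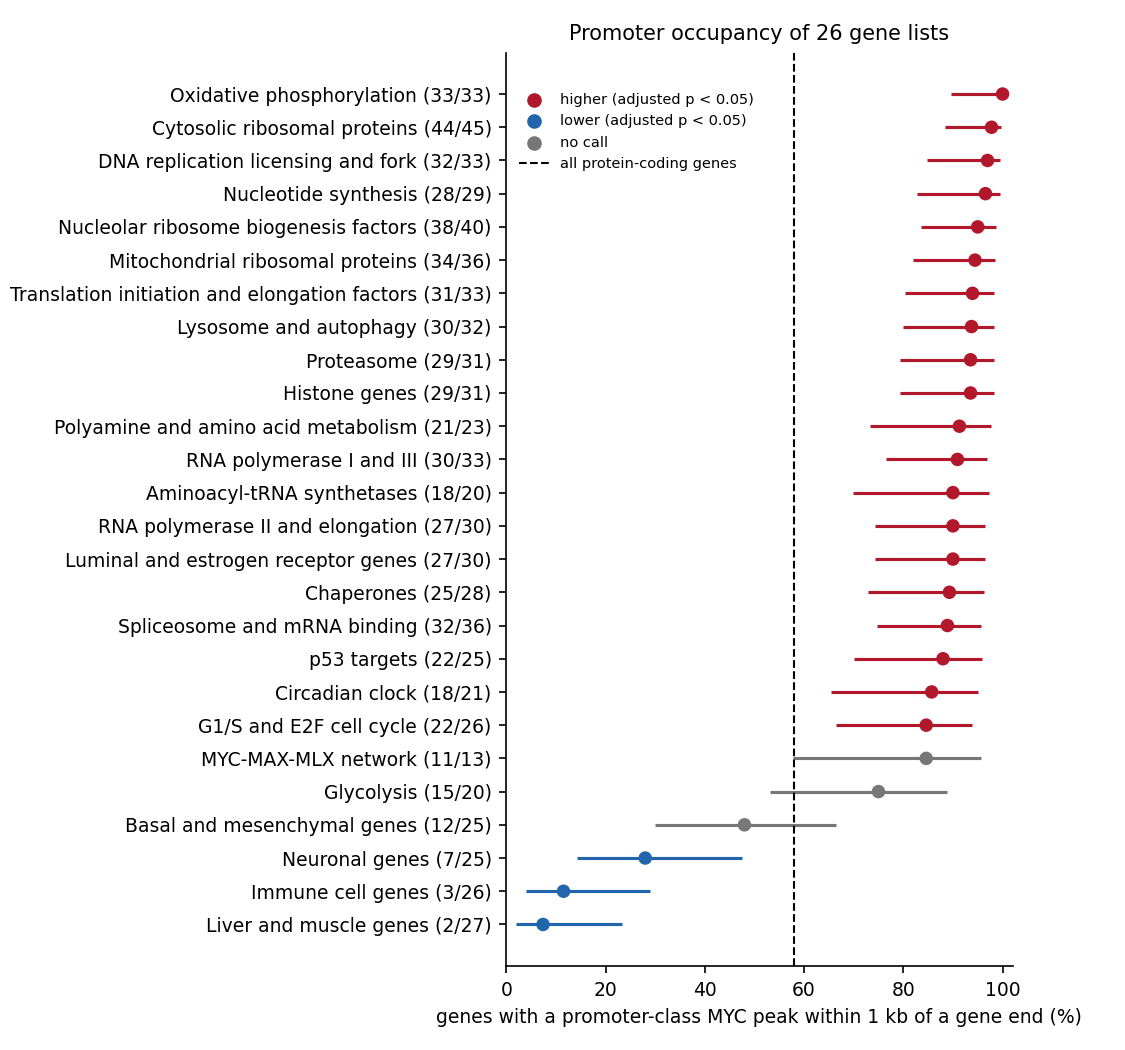
Percent of the members of each gene list with a promoter-class MYC peak within 1 kb of a gene end (x axis); points are shares, horizontal lines 95% Wilson intervals, and numbers in brackets occupied and total members. The dashed line marks all protein-coding genes (58.0%); red lists were occupied more often and blue lists less often than the remaining genes, and grey lists did not pass the test.

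Some members of the highly occupied lists had no peak of any class over the gene or within 1 kb of it. They included RPS9, a ribosomal protein of the small subunit, the splicing factor PRPF31, the kinase CDK7, BDP1, a subunit of the RNA polymerase III factor TFIIIB, and PSMB3, a proteasome subunit. RPS9 and PRPF31 lay in a peak-free stretch of 1.08 Mb on chromosome 19 that held 42 genes. CDK7 and BDP1 lay in another of 2.44 Mb on chromosome 5 with 16 genes, and PSMB3 in another of 3.09 Mb on chromosome 17 with 53. At these genes the lack of a peak was thus shared with their neighbours. VARS1, the valyl-tRNA synthetase, MRPS18B, POLR1H, NELFE, the RNA helicase DDX39B and the heat shock gene HSPA1A also had no peak, and these 6, with HSPA1B, lay in a stretch of chromosome 6 from 28490466 to 33491622 that held 170 protein-coding genes, not counting genes with only a LOC symbol, and 0 peaks. HSPA1B was named after its value was seen. Of 27 members of the highly occupied lists without any peak, 14 lay in peak-free stretches that held at least 10 genes. The rest, such as EEF1D, EIF3C and CARS1, did not. Other members lacked a promoter-class peak at a gene end but held a promoter-class peak inside the gene. These included the ribosome biogenesis factors PES1 (1379) and BYSL (1309), the p53 target AEN (3852), the estrogen receptor gene ESR1 (105) and its target GREB1 (673).

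**Figure D3:**
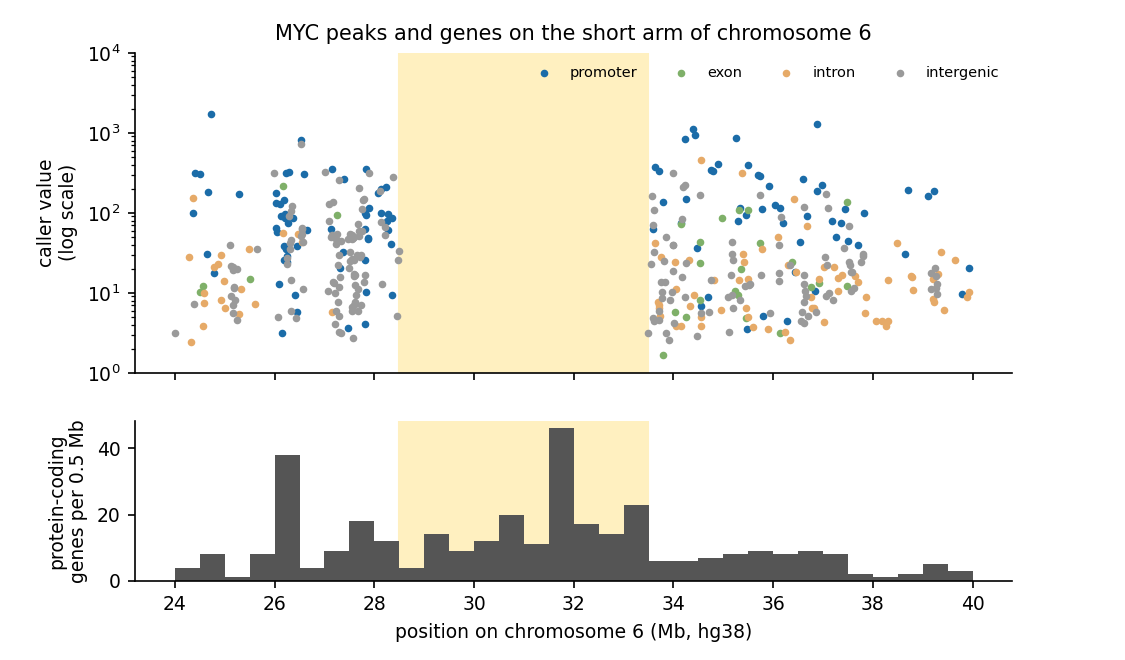
MYC peaks and protein-coding genes on the short arm of chromosome 6 (x axis, position in Mb, hg38); upper panel, caller value of each peak (log scale), coloured by annotation class; lower panel, protein-coding genes per 0.5 Mb. The shaded stretch from 28490466 to 33491622 holds 170 genes and 0 peaks.

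Among occupied genes, nucleolar ribosome biogenesis factors and cytosolic ribosomal proteins had the highest median peak strength of the lists tested, and lists were not tested against each other. Nucleolar ribosome biogenesis factors had a median caller value of 1109, 7.54 times that of the other occupied genes, and cytosolic ribosomal proteins 981, or 6.67 times. Chaperones (641, 4.35 times), translation factors (584, 3.96 times), RNA polymerase I and III genes (554, 3.76 times), spliceosome and mRNA binding genes (502, 3.41 times) and nucleotide synthesis (443, 3.01 times) followed. Each of these 7 lists had an adjusted p of 6.86e-05 in a two-sided permutation test of the median against random sets of as many occupied genes, adjusted over 24 lists, which is the smallest value the resamples allowed for them. Aminoacyl-tRNA synthetases (504, 3.42 times, permutation test, adjusted p = 0.00048), mitochondrial ribosomal proteins (434, 2.95 times, 0.00012), glycolysis (410, 2.77 times, 0.0122) and polyamine and amino acid metabolism (301, 2.04 times, 0.0485) were also higher, which made 11 lists. The polyamine call was lost within 3 kb (1.97 times, permutation test, adjusted p = 0.0571), with caller values of at least 10 (1.88 times, 0.0555) or at or above the median (1.76 times, 0.0967), with the score above its lowest value (1.88 times, 0.0655) and among genes with no other gene within 5 kb (2.51 times, 0.0517). Among those isolated genes aminoacyl-tRNA synthetases (2.60 times, 8 occupied genes, permutation test, adjusted p = 0.103), nucleotide synthesis (3.49 times, 7 genes, 0.0517) and chaperones (3.08 times, 8 genes, 0.0517) did not pass either.

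The 2 strongest peaks of each of these lists included those at WDR43 (3362) and PPAN (2868) among nucleolar factors, RPSA (3553) and RPS23 (3305) among ribosomal proteins, and EIF3E (3624) and EIF3B (3206), subunits of initiation factor eIF3. They also included MRPL3 (3542), IARS1 (2501), the isoleucyl-tRNA synthetase, POLR1B (2180), the second largest subunit of RNA polymerase I, CCT5 (2724), a subunit of the chaperonin TRiC, and the splicing factor gene SRSF7 (2190). Spermidine synthase, SRM, had a caller value of 981. The PPAN, EIF3B, POLR1B and CCT5 peaks also reached a neighbouring gene.

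No list was lower by this test, and 13 did not pass it. Oxidative phosphorylation genes, occupied without exception, had a median of 159, or 1.07 times that of the other occupied genes (permutation test, adjusted p = 0.795), with CYCS, which encodes cytochrome c, at 959. Proteasome genes stood at 185 (1.25 times, 0.426), DNA replication at 247 (1.67 times, 0.0718), G1/S and E2F genes at 242 (1.64 times, 0.156), RNA polymerase II and elongation genes at 214 (1.45 times, 0.245) and p53 targets at 197 (1.33 times, 0.381). DNA replication passed with caller values at or above the median (1.73 times, permutation test, adjusted p = 0.0484) and with the score above its lowest value (1.83 times, 0.0311). These limits left 27 and 28 of its 32 occupied members. Limits on value or score remove genes by peak strength or score before strength is compared, so such changes are no independent check. Luminal genes (105, 0.708 times, 0.314), lysosome and autophagy (101, 0.682 times, 0.245), circadian clock (90.4, 0.611 times, 0.245), histone genes (87.2, 0.588 times, 0.144), basal and mesenchymal genes (53.1, 0.359 times, 0.0669) and neuronal genes (36.0, 0.243 times, 0.0718) had medians below the other occupied genes without passing. Other settings gave lower calls for basal and mesenchymal genes within 3 kb (0.305 times, permutation test, adjusted p = 0.0354) and neuronal genes with the score above its lowest value (0.291 times, 0.0401). Histone genes passed as lower with caller values at or above the median (0.511 times, 0.024) and the score at its highest (0.501 times, 0.0146). The clock ratio was above 1 under these limits on value and score (1.32 to 1.36 times), without passing. Liver and muscle and immune cell genes had too few occupied members to be tested. The highest value of the G1/S list, 2861, was counted for CKS2 but belonged to a peak outside that gene, within 1 kb of it and of SECISBP2. That of the replication list, 1840, counted for CDT1, belonged to a peak over an end of CDT1 that also reached APRT and GALNS. With the deposited score in place of the caller value no list passed, since 1000 is its highest value and every list that had passed had that median. Without chromosomes 1, 17 and 20, which carry amplified regions in this line, glycolysis (2.09 times, permutation test, adjusted p = 0.126) and polyamine and amino acid metabolism (1.99 times, 0.0847) no longer passed.

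**Figure D4:**
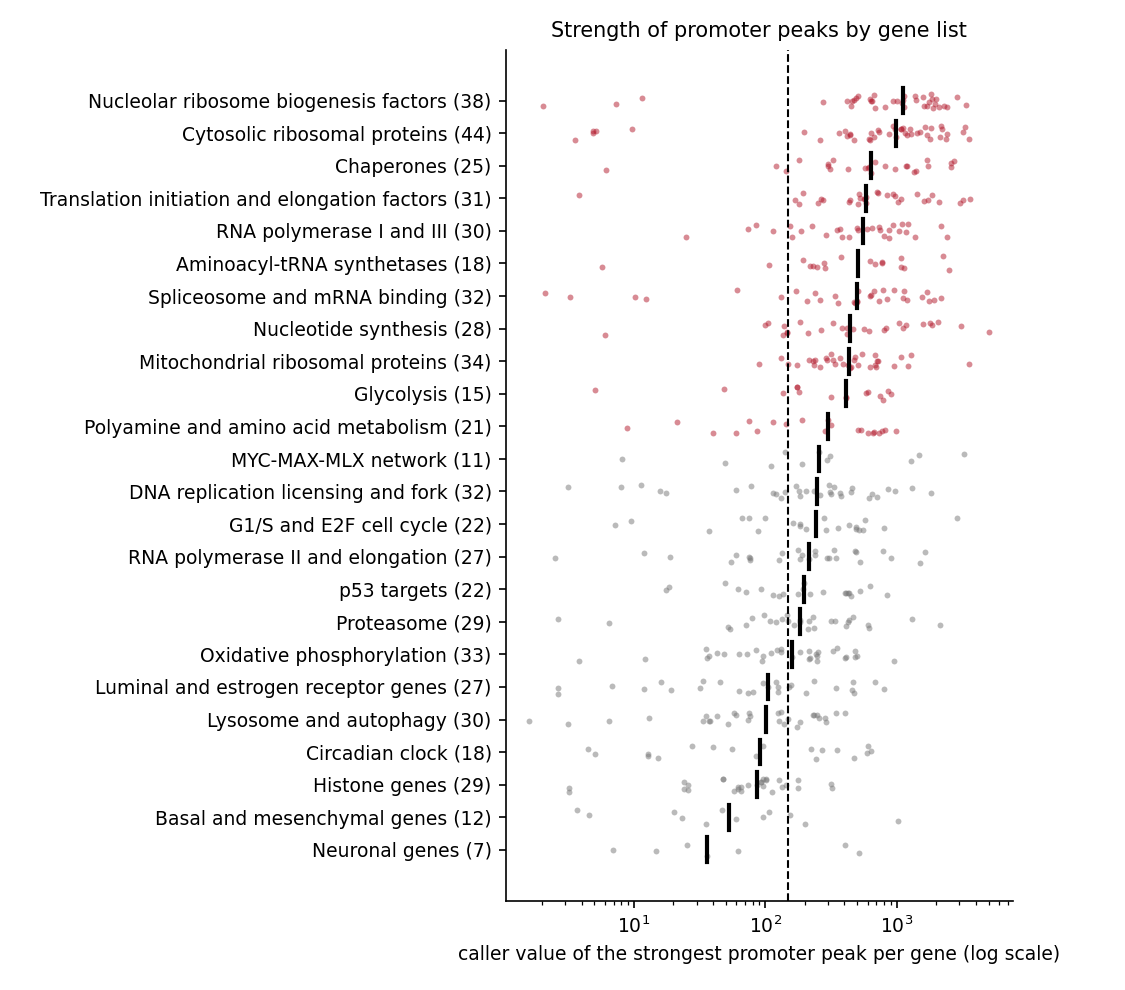
Caller value of the strongest promoter-class MYC peak of each occupied gene (x axis, log scale), by gene list; points are genes, black bars list medians, and numbers in brackets occupied members. The dashed line marks the median of all occupied genes (148); the 11 lists in red, led by nucleolar ribosome biogenesis factors (1109), were higher than the other occupied genes, and grey lists did not pass the test.

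MYC bound the promoters of most of its own network of partner and competitor genes. Of 13 members of the MYC-MAX-MLX network, 11 were occupied (odds ratio 3.99, Fisher exact test, adjusted p = 0.0949), with a median of 254 (1.72 times that of the other occupied genes, permutation test, adjusted p = 0.245). Neither test passed, and among genes with no other gene within 5 kb the strength ratio was 0.924 (5 occupied genes). MXD1, which encodes a MAX partner that opposes MYC, had the highest value (chromosome 2, 69913453 to 69916480, 3229, rank 29 of the occupied genes), followed by MXD3 (1484) and MAX itself (chromosome 14, 65101566 to 65103940, 1276, rank 356). MLXIP stood at 311, MXI1 at 296, MNT at 254, MLX at 141 on a peak shared with COASY, and MXD4 at 111. The peak at the MYC gene (chromosome 8, 127733668 to 127739842) had a value of 190 and ranked 4804. Its paralogs MYCL and MYCN stood at 49.5 and 8.15. MGA and MLXIPL had no promoter-class peak at a gene end and held one inside the gene, at 636 and 145, and when such peaks were counted 13 of 13 members were occupied (Fisher exact test, adjusted p = 0.00346). That setting was chosen after the data were seen, and 62.1% of all protein-coding genes were occupied under it.

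Genes long used as MYC targets differed widely in their peaks. NCL, which encodes nucleolin, had a caller value of 2083 and CAD, an enzyme of pyrimidine synthesis, 2075, on a peak shared with ATRAID. LDHA, lactate dehydrogenase A, stood at 898, ODC1, the first enzyme of polyamine synthesis, at 772, the cyclin-dependent kinase gene CDK4 at 493 and TERT, the catalytic subunit of telomerase, at 126. NPM1, which encodes nucleophosmin, had a peak 4449 bp wide (chromosome 5, 171386843 to 171391291) with a caller value of 2.03 and the lowest score of the list, 113. It belonged to a group of 208 peaks wider than 3 kb with caller values below 10, so its low value is not shown to mean weak binding. CDKN1A, the gene of the cell cycle inhibitor p21, had no peak at a gene end and a promoter-class peak of 91.2 inside the gene.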

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

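Chosen after the data were seen were the limits on the deposited score, the settings with isolated genes, peaks of any class, peaks inside genes and no LOC symbols, and, for list strength, the limits on the caller value and the omission of chromosomes 1, 17 and 20. The deposited score in place of the caller value had been planned. No paired analysis was possible because the peak list has no value per sample. E-box windows and flanks, a CpG-matched background, reference start sites, genes assigned by the list itself and every AM against DMSO alternative (replicate block, DESeq2 size factors or another pseudocount, each replicate left out, no filter) were not run. The number of peaks was 23792 with caller values at or above the median and 18938 with the score at its highest value, by construction. The promoter share was 30.8% with caller values of at least 10, 40.6% with values at or above the median, 23.7% without chromosomes 1, 17 and 20, 31.1% with the score above its lowest value and 47.3% with the score at its highest. Promoter peaks stayed stronger than other peaks in each of 3 alternatives, with ratios of medians of 3.52 (deposited score), 7.96 (without those chromosomes) and 4.87 (score above its lowest value). For list occupancy, 265 odds ratios over all lists and alternatives kept their direction and side of the threshold, 14 lost the call, 6 gained it and 1 changed direction, that of basal and mesenchymal genes, 1.01 when any peak over the gene counted. For list strength with the caller value, 191 ratios kept both, 10 lost the call, 6 gained it and 4 changed direction. These were circadian clock genes, at 1.36 with caller values at or above the median, 1.32 with the score above its lowest value and 1.34 with the score at its highest, and the MYC-MAX-MLX network, at 0.924 among genes with no other gene within 5 kb. None of these 5 values passed its test there or with all peaks. Lists higher by strength numbered 6 among those isolated genes. Fewer genes and fewer lists were tested there, since lists with too few occupied members were left out. With the deposited score they numbered 0, and 23 of 24 ratios were 1, with no direction, since medians stood at its highest value. Lists lower by strength numbered 1 with caller values at or above the median (histone genes, 0.511 times), 1 within 3 kb (basal and mesenchymal genes, 0.305), 1 with the score above its lowest value (neuronal genes, 0.291) and 1 with the score at its highest (histone genes, 0.501). The cause of these 4 calls was not tested. Depth was not given, so a gene without a peak is not shown to be unbound.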

Other observations

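Both tests of peak-free regions were chosen after the result was seen, as were the sets of named non-coding genes and their tests; the tests on tRNA genes were set after peaks had been seen near tRNA genes but before their own results, and the test of growth lists before any list was tested. Peaks were frequent at tRNA genes, which RNA polymerase III transcribes and which the authors' classes do not name. Of 443 nuclear tRNA genes, 237 had a peak within 200 bp (53.5%, 95% Wilson interval 48.8 to 58.1%), against 72 of 886 positions shifted by 20 kb (8.13%, odds ratio 13.007, Fisher exact p = 1.7e-73). The 237 genes rested on 169 distinct peaks, 132 of them intergenic, with a median caller value of 61.5, and the interval and p count genes under 1 peak as separate. With 1 tRNA gene counted per 100 kb, 84 of 148 had a peak (56.8%), against 5.07% of shifted positions (Fisher exact p = 4.15e-34). A promoter-class peak lay at 52 of the 237, and the highest value, 1169 at TRL-AAG2-4, was that of the promoter peak of POLR3E. The highest value of an intergenic peak was 893, at TRT-TGT2-1. Of 155 tRNA genes on chromosome 6, 40 lay in the peak-free stretch from 28490466 to 33491622, and 74 of the 115 others had a peak. On chromosomes 1 and 7, 21 of 98 and 4 of 22 had a peak, against 30 of 33 on chromosome 17. Loss of reads shared between copies was not tested for tRNA genes, so those without a peak are not shown to be unbound. Of 17 other RNA polymerase III genes, 16 had a peak within 1 kb of an end. Of positions shifted by 20 kb, 9 of 34 had a peak (Fisher exact p = 3.88e-06). The 16 had a median of 59.3, and 10 of them lay below the median of occupied protein-coding genes (148). The highest values were those of RN7SL1, an RNA of the signal recognition particle (1292), RNY5 (987) and RMRP (445). The RN7SL1 and RMRP peaks were of the promoter class, as were others, such as those of RN7SK and RPPH1. Peaks of neighbouring promoters were not set apart for these genes. Some of the genes also shared a peak, and the p counts them as separate. This set too was chosen after peaks had been seen, so its p is no independent support.

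Most host genes of small nucleolar RNAs had a peak. Of 15 such genes, 14 had one within 1 kb of an end, against 8 of 30 shifted positions (Fisher exact p = 2.32e-05), with a median caller value of 955, whose difference from other genes was not tested, among them SNHG17 (2666), SNHG7 (2254), SNHG16 (1848), SNHG15 (1623) and GAS5 (1461). SNHG12 (4.39), SNHG3 (15.6), SNHG1 (21.2) and ZFAS1 (42.3) lay below the median of occupied protein-coding genes (148). Among 9 other long non-coding RNAs, 7 had a peak, against 5 of 18 shifted positions (Fisher exact p = 0.0369), with a median of 261. Both sets were chosen after peaks had been seen, so these p-values are no independent support for enrichment. The 7 were MIR17HG, the host of the miR-17 cluster (2938), PVT1, a neighbour of MYC on chromosome 8 (2444), MALAT1 (435), HOTAIR (261), KCNQ1OT1 (144), TERC, the RNA of telomerase (142), and NEAT1 (5.66), and the imprinted genes H19 and MEG3 had none. The authors placed the peaks of GAS5, SNHG1, SNHG3 and ZFAS1 at promoters of protein-coding transcripts. Those of SNHG8 and HOTAIR were of the exon class, and those of EPB41L4A-AS1 and KCNQ1OT1 of the intron class. Peaks of neighbouring protein-coding genes were not set apart for the host genes and lncRNAs. Of 18177 annotated lncRNA genes, 21.03% had a peak within 200 bp of an end, against 6.25% of shifted positions.

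Peaks at tRNA genes could come from wide promoter peaks of neighbouring genes, or from reads shared between identical tRNA copies. Of tRNA genes more than 5 kb from every protein-coding gene end, 43.8% had a peak, against 7.06% of shifted positions (Fisher exact p = 8.88e-42), and with 1 gene per 100 kb 43.3% against 2.58%, which argues against neighbouring promoters as the whole source. Of tRNA genes that are the only copy of their numbered family, 49.8% had a peak, against 7.96% (Fisher exact p = 2.77e-30). This argues against reads shared between identical copies as the whole source. Copies of different families with nearly the same sequence were not set apart. Unspecific recovery of highly transcribed DNA stays open, since no control antibody was used here, and no biological explanation was tested.

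The high occupancy of growth genes might be that of housekeeping promoters in general. Pooled growth lists (nucleolar factors, RNA polymerase I and III, nucleotide synthesis, aminoacyl-tRNA synthetases) had 114 of 122 genes occupied and pooled housekeeping lists (lysosome, oxidative phosphorylation, proteasome) 92 of 96 (Fisher exact p = 0.556), so occupancy leaves that explanation open. The median caller value of occupied growth genes was 657 against 147, a ratio of 4.47 (95% bootstrap interval 3.01 to 6.22, permutation p = 1e-05, the smallest possible), which argues against 1 strength common to all housekeeping promoters. Chaperones (641) and spliceosome genes (502) were also strong, so high strength was not limited to growth lists. Nucleolar factors (1109) stood above both. RNA polymerase I and III genes (554), aminoacyl-tRNA synthetases (504) and nucleotide synthesis (443) stood below chaperones. Against 7 pooled upkeep lists that include chaperones and spliceosome genes the ratio was 3.55 (permutation p = 1e-05). That comparison was added after the list medians were seen. The other lists of the pool had medians from 87.2 to 214, so the ratio is no independent check. Differences in expression or promoter openness between the lists were not measured here and stay open, and no biological explanation was tested.

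The peak-free region with the most genes spanned 5.00 Mb of chromosome 6 (28490466 to 33491622), which contains the major histocompatibility complex, while the 5 Mb on either side held 201 and 206 peaks. If its genes and those of other peak-free regions were silent, it should hold genes of the highly occupied lists as rarely as they do. Of its 170 genes, 7 were of those lists, against 7 of 972 in the 48 other gaps of at least 10 genes (Fisher exact p = 0.00196, or 0.0018 with LOC genes, which are otherwise left out here). The other gaps also held list genes such as RPS9, CDK7 and PSMB3, and expression was not measured. The test therefore cannot decide whether the region is silent. An earlier form of this test was set aside because a region chosen for lacking peaks fixed its outcome. Reads that match another copy of the region in the assembly could be lost, and the pseudoautosomal region of chromosome X, which the assembly also holds on chromosome Y, had 0 of 15 genes with a peak against 429 of 824 elsewhere on X (Fisher exact p = 1.89e-05, or 9.69e-06 with LOC genes). That fits the loss of shared reads there, and the same loss on chromosome 6 would need alternate copies of the region in the alignment index, which is not given in the sources used here. Loss or filtering of the region for other reasons stays open, and no biological explanation was tested.

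Of 1734 peaks wider than 3 kb, whose median caller value was 209, 208 (12.0%) had a caller value below 10, among them that of NPM1, and 207 of these had the lowest score. Of the 208, 170 were of the promoter class. The cause was not tested, and a low value of so wide a peak is not shown to mean weak binding. Of 569 occupied genes of the lists with higher occupancy, 32 had a caller value below 10. Of the 20 strongest intergenic peaks, 8 lay on chromosome 20 and 4 on chromosome 8. Promoter peaks on chromosome 20 had a median caller value of 171 and other peaks there 17.3, and on chromosome 8 these were 139 and 16.5. The promoter median was highest on chromosome 16 (185). On chromosomes 1 and 17 it was 105 and 111, below the 124 of all promoter peaks. DNA copy number, with which the caller value rises, was not measured here.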
